A study of Homo sapiens with 6 samples.

How the data were processed

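Gene expression was measured in 6 samples of SK-Hep1 cells on 1-colour Illumina bead arrays, 3 transfected with control siRNA and 3 with siRNA against YAP1 and TAZ, each profiled 3 days after transfection. Groups were taken from the transfection given in the labels. Total RNA was isolated, amplified and labelled with biotin, per the labels' protocols. BeadStudio is named in the submitters' processing notes, and its version and settings are not given in the sources used here.

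The deposited table of non-normalised values holds 1 summarised bead intensity per probe and array on a linear scale. These values were all above 0 and differed in median between arrays, from 62.2 to 82.95, and the table holds neither control probes nor detection p-values. The authors' processed values were deposited on a log2 scale. They had the same median, 6.12, on all 6 arrays, and 99.9% of them lay within 0.1 of quantile-normalised log2 intensities of the same arrays (largest difference 0.105), so that scale, direction and absence of centring by gene were read from the values. Whether the authors corrected the background before that step is not given in the sources used here.

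The intensities, not the authors' values, were analysed, in R 4.3.3 with limma 3.58.1. The plan, fixed before the data were examined together with the gene lists, the rule for naming genes and the alternative settings, was background correction from negative control probes or detection p-values (limma's neqc). Without either, normexp was fitted to each array's own probe intensities (saddle-point method, offset 16), followed by quantile normalisation and log2. This correction treats the lower part of each array's distribution as background, which sets the size of changes in dim probes. Detection was estimated the same way. On the log2 intensities of an array, the mode of the density (bandwidth 0.05) was taken as the background level, and the values below the mode, mirrored around it, as the spread of background. A probe was called detected at a p of 0.05 from that spread. Background levels were 71.5, 58.96 and 75.9 on the control arrays and 56.8, 64.8 and 58.0 on the knockdown arrays, and detection thresholds ran from 76.5 to 128.3. Between 28.8% and 35.6% of probes were detected per array. Probes detected on at least 3 of the 6 arrays were tested.

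Gene names came from the platform annotation supplied with the data, updated through Entrez Gene identifiers. Of 47231 probes, 30113 had 1 gene symbol, 8 had several and 17110 were unnamed here, and 30074 of the named probes had an identifier in the reference gene table. Genes without a uniquely named probe were not analysed here. Of the 15899 detected probes, 12831 were named, for 9718 genes. A gene was represented by its brightest detected probe. Of 2573 genes with more than 1 detected probe, 33 had probes past the threshold in opposite directions. Genome coordinates of the probes were not used here.

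Differences were tested with lmFit and eBayes at default settings on all 6 arrays with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all detected probes, with a threshold of 0.05. All tests were two-sided. Changes are knockdown minus control on the log2 scale, and folds are powers of 2 of these. A gene below detection on all arrays of a group has only a bound there. Its fold is given as at least the ratio of the brighter group's mean to the mean, over the dimmer group's arrays, of the higher of the probe's own value and the lowest value of any detected probe on that array. Replicates carried the same numbers in both groups, but the labels do not say that a number marks a shared day, so the model without replicate number was used.

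Gene lists were tested with camera (preset correlation 0.01) on the gene-level values, adjusted over the 22 lists with at least 5 measured members. The 5 lists chosen after the data were seen were tested the same way and adjusted over those 5 alone. Lists with fewer, the hepatocyte, endothelial and leukocyte markers, were counted only. Camera asks whether a list moves relative to the other genes. It was repeated with the correlation estimated from the data, and fry, which asks whether a list's genes move on balance in a direction without comparing them with other genes, was run as well. Counts of members were given from the adjustment over all probes and from an adjustment over the list alone. Each list was also set against 10000 random lists of the same size, matched on mean signal in 20 bins.

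Genes were named by rule: the siRNA targets, the 12 largest rises and 12 largest falls among genes past the threshold with non-overlapping groups and detection on all arrays of the higher group (ranked by fitted change, also where a gene has only a bound, and leaving out provisional symbols), up to 3 members past the threshold per list and direction, and CCN1, CCN2 and ANKRD1 in any case. Members of lists that did not pass, TAFAZZIN and the genes of lists chosen later were named after their values were seen.

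The procedure was tested on simulated data, with 10 simulated sets of 6 arrays that had this data set's means and probe spreads and known changes in 200 probes each. At an adjusted p of 0.05 it recovered 72.5% of log2 changes of 0.5, 95.5% of changes of 1 and 95.2% of changes of 2, among 15465 to 15617 probes tested per set, and 6.1% of all calls were false. With no change simulated there were 0 calls by limma, and camera called a shifted list and 0 of 21 others, each in a single run. Noise was drawn independently for each probe, so correlation between genes could not affect camera there. About as many of the 200 probes rose as fell. Normalisation was therefore not tested under a change as broad as in the data, where 54.8% of genes passed.

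Alternatives were no background correction, an offset of 50, median scaling, the authors' processed values, no detection filter, detection at a p of 0.01, detection on all 6 arrays, the trend and robust options of eBayes, array weights, the mean of a gene's detected probes, a replicate block, leaving out each array in turn, and for lists the other set tests and leaving out members shared between lists. Median scaling set each array's median over all 47231 probes, detected or not, to a common value. The background level of each array as a covariate was added after seeing the data. Slides were not given in the sources used here, so slide was not used as a block. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.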

Results

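SK-Hep1 cells, an established human line from a liver adenocarcinoma, were transfected with siRNA against YAP1 and TAZ or with a control siRNA, and their RNA was profiled 3 days later. YAP1 and TAZ are transcriptional co-activators that the Hippo kinase cascade holds in check and that act largely through TEAD transcription factors. Each group held 3 samples, and each sample was hybridised to an Illumina bead array of 47231 probes. Median bead intensity ran from 62.2 to 82.95 across the 6 arrays, and 13620 to 16827 probes per array stood above the estimated background. Probes above background on at least 3 arrays numbered 15899 and stood for 9718 named genes. Replicates of a group correlated at r of 0.990 to 0.995 across probes and arrays of different groups at 0.932 to 0.944, and the leading principal component, which separated the groups, held 84.75% of the variance. Precision was limited by the number of arrays. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

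The comparison asked which transcripts differed after joint depletion of YAP1 and TAZ, and the siRNA targets came first. YAP1 mRNA fell 5.33-fold, and mRNA of WWTR1, the gene that encodes TAZ, fell at least 2.34-fold. For YAP1, normalised log2 intensities were 10.77, 10.85 and 10.79 on the control arrays and 8.42, 8.33 and 8.42 on the knockdown arrays, with group means of 10.81 ± 0.043 and 8.39 ± 0.0504 (SD, n = 3 each). The log2 change in YAP1 was -2.42 ± 0.0936 (SE), with a limma adjusted p of 2.15e-08. WWTR1 averaged 7.41 ± 0.062 in the controls and 5.57 ± 0.25 after knockdown (SD, n = 3 each), where its probe was below the detection threshold on all 3 arrays (adjusted p = 6.75e-07). The gene once also called TAZ, TAFAZZIN, encodes a mitochondrial cardiolipin remodelling enzyme and was not a target of the siRNA. It was 1.35-fold higher (log2 change 0.43 ± 0.149 SE, adjusted p = 0.0301), with 0.31 for its other probe. The groups overlapped, with control replicate 2 at 7.42 and knockdown replicate 3 at 7.41. Its intensities before processing ran from 159.6 to 209 in the controls and from 173.1 to 215.5 after knockdown.

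Genes known to be activated by YAP and TAZ fell. CCN1 and CCN2, which encode secreted matrix-associated proteins, fell 8.07-fold and 7.29-fold, and ANKRD1, a nuclear ankyrin repeat protein, fell 3.63-fold. CCN1 went from 12.38 ± 0.105 to 9.37 ± 0.204, CCN2 from 12.41 ± 0.173 to 9.54 ± 0.0774 and ANKRD1 from 10.74 ± 0.373 to 8.88 ± 0.273 (log2 mean ± SD, n = 3 each). Their adjusted p-values were 2.34e-08, 2.28e-08 and 9.91e-06, and the other CCN2 probe gave a log2 change of -3.08. Of the 19 measured members of the fixed list of YAP and TAZ target genes, 13 fell, 3 rose and 3 did not pass the threshold, with the same counts adjusted over the list alone. The list's median log2 change was -0.70, and camera placed it below the other genes (adjusted p = 0.000969, and adjusted p = 0.0853 with an estimated correlation). The members that rose were NT5E, an ecto-nucleotidase, at 1.59-fold, PTPN14, a phosphatase that binds YAP, at 1.47-fold, and MYOF, a membrane repair protein, at 1.31-fold. Other probes gave log2 changes of 0.31 against 0.56 for PTPN14 and of 0.19 and 0.35 against 0.39 for MYOF. With arrays scaled to a common median, the number of rising members was 1, and PTPN14 (log2 change 0.35, or 0.46 relative to the median of all genes, adjusted p = 0.138) and MYOF (0.20, or 0.30, adjusted p = 0.449) no longer passed. AMOTL2, ASAP1 and ARHGEF17 had log2 changes of -0.30, -0.16 and -0.10 and did not pass.

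**Figure D1:**
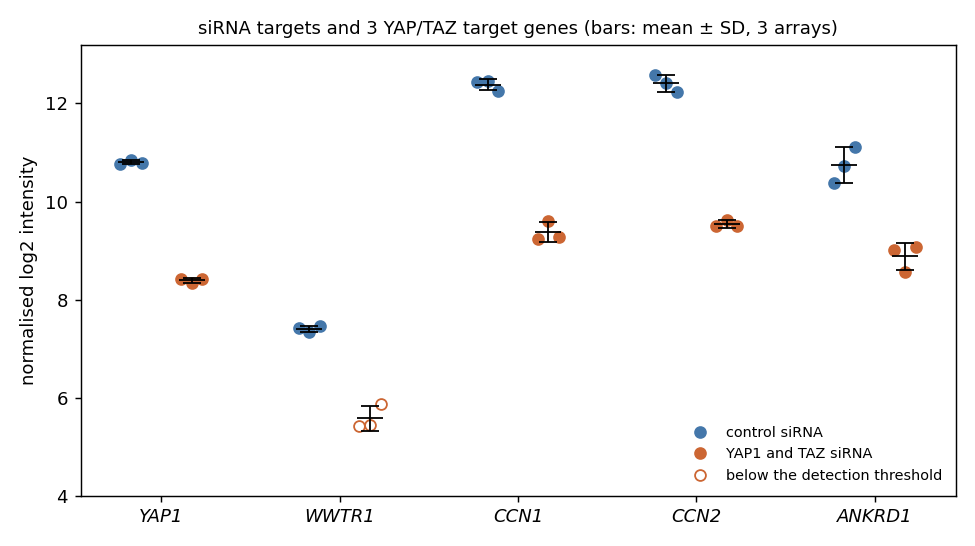
Normalised log2 intensity (vertical axis) of YAP1, WWTR1, CCN1, CCN2 and ANKRD1 on each array, control siRNA in blue and YAP1 and TAZ siRNA in orange, with bars for the mean ± SD of 3 arrays and open circles for values below the detection threshold. All 3 knockdown arrays lie below all 3 control arrays for each of the genes, and WWTR1 falls from a mean of 7.41 to 5.57, below detection.

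Across the 9718 genes, 2658 rose and 2670 fell, so that 5328 (54.8%) passed an adjusted p of 0.05. At 2-fold or more, 505 rose and 538 fell (462 and 507 with genes below detection in a group at their bound), and with arrays scaled to a common median 691 fell and 34.69% of the 1058 such genes rose. The 3 arrays of one group lay wholly above the 3 of the other for 6061 genes (62.4%), where chance gives 10%. With median scaling in place of quantile normalisation, 1438 genes rose and 2475 fell, so that the share of rises among calls was 36.75% in place of 49.89%. It placed the median log2 change of all genes at -0.107 in place of 0.0016.

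The largest rise was in SCG2, a secretory granule protein of neuroendocrine cells, at 23.5-fold (log2 change 4.55 ± 0.102 SE, adjusted p = 1.05e-09), with the probe above background on 1 of the 3 control arrays. PTGES, which makes prostaglandin E, rose 20.1-fold (log2 change 4.33 ± 0.158 SE, adjusted p = 1.65e-08), from 6.85 ± 0.297 to 11.18 ± 0.223. ABCC3, an export pump for organic anions and bile salts, rose at least 13.1-fold, and PLAAT4, a retinoid-inducible phospholipase, at least 9.17-fold, both from below detection on all control arrays. CYP1B1, a cytochrome P450 that oxidises xenobiotics and steroids, rose 10.7-fold, H4C8, a histone H4 gene, 9.77-fold, and MMP9, a secreted gelatinase detected on 2 of 3 control arrays, 9.29-fold. GBP2, an interferon-inducible GTPase, rose 8.88-fold from a control level detected on 1 of 3 arrays. TDO2, which breaks down tryptophan, rose 8.07-fold, CASTOR1, an arginine sensor, 7.19-fold, CTSO, a cathepsin, 6.95-fold, and ZNF467, a zinc finger protein, at least 3.72-fold.

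Among the largest falls, SFTA1P, a transcribed pseudogene, fell 10.7-fold (log2 change -3.42 ± 0.106 SE, adjusted p = 8.71e-09). GINS2 and CDC45, parts of the replicative helicase, fell 9.05-fold and 8.44-fold, each detected on 2 of 3 knockdown arrays. MCM10, a replication initiation factor, fell 7.42-fold, a log2 change of -2.89, with -1.91 for its other probe. KRT34, a hair keratin, fell 8.24-fold, and EDN1, the precursor of a vasoconstrictor peptide, fell 7.63-fold, from 10.78 ± 0.0767 to 7.85 ± 0.18. H4C3, another histone H4 gene, fell 7.14-fold and KIFC1, a mitotic kinesin detected on 2 of 3 knockdown arrays, 7.08-fold. Histone H4 genes have closely similar coding sequences, and how far the probes of H4C3 and H4C8 read other copies is unknown. EXO1, an exonuclease of DNA repair, fell at least 5.57-fold and NPPB, the precursor of a natriuretic peptide, at least 4.27-fold, both to below detection on all knockdown arrays. Ranked by bound, ZNF467, EXO1 and NPPB would not be among the 12 largest rises or falls.

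**Figure D2:**
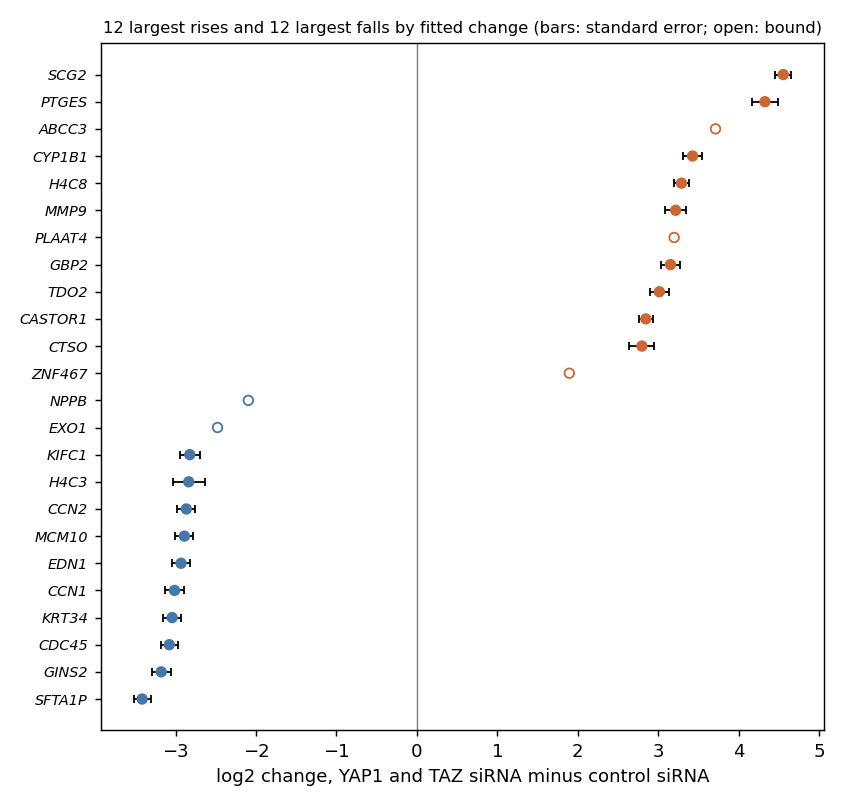
Log2 change after YAP1 and TAZ siRNA (horizontal axis, knockdown minus control) of the 12 genes with the largest fitted rises, in orange, and the 12 with the largest fitted falls, in blue, with bars for the standard error. Open circles without bars mark the bounds of ABCC3, PLAAT4, ZNF467, EXO1 and NPPB, which were below detection on all arrays of a group. Points run from 4.55 for SCG2 to -3.42 for SFTA1P.

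Genes of the cell division cycle fell together. All 36 measured genes of mitosis and G2/M fell, with a median log2 change of -2.12, or 4.34-fold. CDC20, an activator of the anaphase-promoting complex, fell 6.75-fold, PRC1, a spindle midzone protein, 5.66-fold and CENPA, the centromeric histone, 5.63-fold. Of 32 measured genes of DNA replication and G1/S, 30 fell and none rose, with a median of -1.98, or 3.95-fold. That median was the same to 2 decimals, -1.98, when the 7 members below detection on all knockdown arrays were set to their bound. ORC6 and E2F1, at log2 changes of 0.05 and 0.07, did not pass; members short of the threshold are named here and below after their values were seen. Camera gave adjusted p-values of 1.53e-23 for mitosis and 4.53e-18 for replication (adjusted p = 0.0449 and 0.046 with an estimated correlation), and adjustment over each list alone gave the same counts. Requiring detection on all 6 arrays left 21 replication genes, of which 19 fell.

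Ribosome biogenesis genes also fell, 20 of 22 measured (21 adjusted over the list alone), with a median log2 change of -0.81, or 1.75-fold. NOP16 and MRTO4, nucleolar proteins of the large subunit pathway, fell 2.89-fold each, and NOLC1, a nucleolar phosphoprotein, fell 2.79-fold. RRP9 and RRS1, at -0.26 and -0.19, did not pass. The list lay below the other genes with a camera adjusted p of 2.77e-08 (adjusted p = 0.0449 with an estimated correlation).

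Extracellular matrix genes rose. Of 23 measured members of the collagen and matrix list, 19 rose and 1 fell (21 and 1 adjusted over the list alone), with a median log2 change of 0.88, or 1.84-fold. COL6A1 and COL6A2, chains of collagen VI, rose 6.01-fold and 4.07-fold, and TGFBI, a matrix protein induced by TGF-beta, rose 3.74-fold. LOX, the collagen cross-linking oxidase, fell 1.32-fold (log2 change -0.40, adjusted p = 0.00678, but 0.0571 at the same change without the detection filter and 0.0565 at -0.35 with the array background level as a covariate). COL4A2, LAMB1 and THBS1, with log2 changes of 0.26, 0.32 and 0.39, did not pass. Camera gave an adjusted p of 5.14e-08 for this list (adjusted p = 0.107 with an estimated correlation).

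Among integrin and focal adhesion genes, 10 of 20 rose and 2 fell (11 and 2 adjusted over the list alone), with a median log2 change of 0.34. With the mean of a gene's probes 14 of 20 rose and the median was 0.56. The integrin subunit genes ITGB4 and ITGA2 rose 3.81-fold and 3.62-fold, with ITGB4 detected on 2 of 3 control arrays, and ITGB3 rose at least 2.79-fold from below detection. FERMT2, a kindlin that activates integrins, fell 1.56-fold and BCAR1, an adhesion adaptor, 1.40-fold. The camera adjusted p was 0.00353 (adjusted p = 0.303 with an estimated correlation). Of 10 measured mesenchymal markers, 8 rose and none fell, also adjusted over the list alone, with a median of 0.58, or 0.46 with LUM at its bound (camera adjusted p = 0.00393, adjusted p = 0.107 with an estimated correlation). SNAI2, a transcription factor of epithelial to mesenchymal transition, rose 1.77-fold, LUM, a matrix proteoglycan, rose at least 1.04-fold from below detection, and VIM and TWIST2 had log2 changes of 0.02 and 0.28 and did not pass. Median scaling left 5 mesenchymal markers higher, and without the detection filter 8 of 18 rose, with a median of 0.35.

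Genes of the TGF-beta and BMP response rose in 11 of 16 cases and fell in 1 (12 and 1 adjusted over the list alone), with a median log2 change of 0.85. Without the detection filter 12 of 23 rose, none fell and the median was 0.42, and with detection on all 6 arrays 9 of 10 rose, none fell and it was 1.20. ID1 and ID3, inhibitors of basic helix-loop-helix factors and targets of BMP signalling, rose 6.32-fold and 3.43-fold, although the other ID1 probe gave a log2 change of 1.02 against 2.66, and ID3 was detected on 2 of 3 control arrays. PMEPA1, a feedback inhibitor of TGF-beta signalling, rose 2.73-fold. GREM1, a BMP antagonist detected on 2 arrays of each group, fell 1.29-fold (log2 change -0.37, adjusted p = 0.0247). Its call was lost without control replicate 1 (-0.25, adjusted p = 0.104) or knockdown replicate 1 (-0.32, 0.0806) and, with no smaller change, without knockdown replicate 3 (-0.37, 0.0599) and under median scaling (-0.39, 0.0984). SMAD2, SMAD4, SKIL and SKI lay between -0.24 and 0.32 and did not pass. The camera adjusted p was 9.82e-05 (adjusted p = 0.107 with an estimated correlation).

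Inflammatory genes rose. Of 21 measured NF-kB and cytokine genes, 14 rose and none fell, also adjusted over the list alone, with a median log2 change of 1.03, or 0.94 with 2 members at their bound. CCL2, a monocyte chemokine, rose 6.92-fold, from 7.51 ± 0.0797 to 10.30 ± 0.109. IRAK2, a kinase of interleukin-1 receptor signalling, rose 4.71-fold, and CCL20, a lymphocyte chemokine, rose at least 3.12-fold from below detection. CXCL8, CXCL1, IL1B and ICAM1 were among the 7 members that did not pass, with log2 changes of -0.16, -0.26, -0.07 and 0.02. Camera gave an adjusted p of 1.9e-05 (adjusted p = 0.107 with an estimated correlation).

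Of 24 measured interferon response genes, 19 rose and 1 fell (20 and 1 adjusted over the list alone), with a median log2 change of 0.78, or 1.71-fold. OAS2, a sensor of double-stranded RNA, rose 3.99-fold, with log2 changes of 1.39 and 0.89 for its other probes and detection on 2 of 3 control arrays. IFIT2, an interferon-induced antiviral protein, rose 2.50-fold and IRF9, a subunit of the interferon-activated factor ISGF3, 2.27-fold. OAS3, HERC5, XAF1 and IFIT5 lay between -0.13 and 0.30 and did not pass. The member that fell, EIF2AK2, a kinase activated by double-stranded RNA, was at -0.32 (adjusted p = 0.0388). Its call was lost when any of control replicate 1 (log2 change -0.36, adjusted p = 0.0513), 2 (-0.34, 0.0778) or 3 (-0.27, 0.121) or knockdown replicate 2 (-0.32, 0.0663) or 3 (-0.23, 0.166) was left out. The camera adjusted p for the list was 1.22e-06 (adjusted p = 0.0449 with an estimated correlation).

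Lysosome and autophagy genes rose in 15 of 21 cases and fell in 2, also adjusted over the list alone, with a median log2 change of 0.45. CTSD and CTSA, lysosomal proteases, rose 4.25-fold and 2.50-fold, and ULK1, a kinase that starts autophagy, rose 2.10-fold. The 2 that fell, MCOLN1 (log2 change -0.44, adjusted p = 0.0257) and MAP1LC3B (-0.41, adjusted p = 0.0162), lost their calls when single arrays were left out. Without control replicate 1 they were at -0.40 (0.0754) and -0.33 (0.0674), without control replicate 3 at -0.39 (0.0835) and -0.35 (0.0612), and MCOLN1 was at -0.43 (0.0559) without knockdown replicate 1 and -0.29 (0.0841) without 2. ATP6V1H, GLA, ATP6V0D1 and NPC1 lay between -0.25 and 0.18 and did not pass. Camera gave an adjusted p of 0.00168 (adjusted p = 0.182 with an estimated correlation), median scaling left 9 members higher, and none fell without the detection filter or with the array background level as a covariate.

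**Figure D3:**
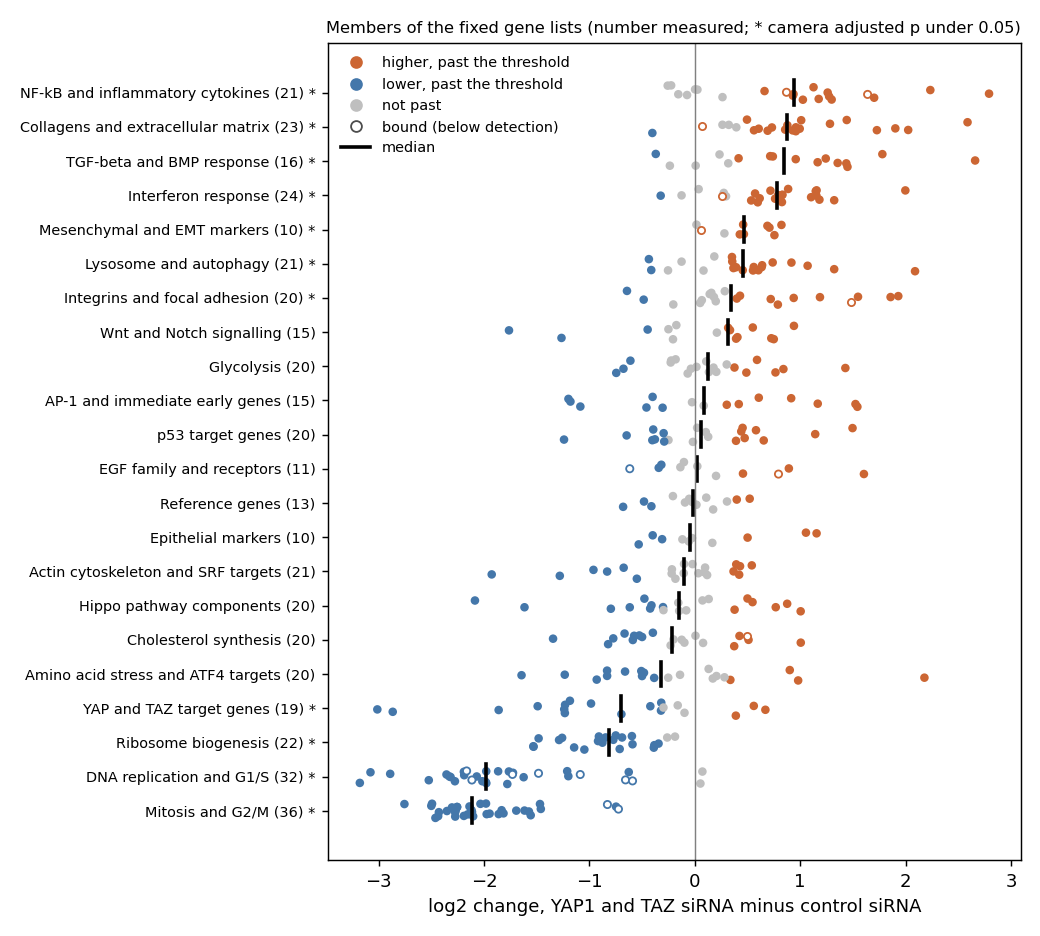
Log2 change after YAP1 and TAZ siRNA (horizontal axis) of every measured member of the 22 tested gene lists, 1 point per gene, orange for higher and blue for lower past the threshold and grey for the rest. Open circles are genes below detection on all arrays of a group, drawn at their bound, and a black bar marks each list's median with these bounds. Medians run from -2.12 for mitosis to 0.94 for NF-kB, and asterisks mark the 11 lists past a camera adjusted p of 0.05, of which 4 held with an estimated correlation.

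The remaining tested lists had members that moved both ways, and camera did not separate them from the other genes. Against 10000 random lists of the same size and signal, 9 of these 11 medians lay within the central 95%, that of Wnt and Notch genes lay above it (percentile 98.33, upper bound 0.29) and that of ATF4 targets below it (percentile 0.75, lower bound -0.26). The medians of the 11 lists that passed camera all lay outside it, at a percentile of 0 or of 99.58 and above. Camera and the random lists both compare a list with other genes, so the latter are not separate evidence. Hippo pathway components had 6 members higher and 8 lower of 20 (median log2 change -0.15, from -0.26 to 0.01 over the settings run, camera adjusted p = 0.618), and 3 were higher under median scaling. TEAD2 rose 2.01-fold and SAV1, a scaffold of the Hippo kinases, 1.84-fold, while WWC1, an upstream activator of the pathway, fell 4.25-fold and TEAD4 3.07-fold, with -0.54 for the other TEAD4 probe. The lower count was 5 without control replicate 1. Of 20 p53 target genes, 8 rose and 7 fell (median 0.06, from -0.07 to 0.10 over the settings, adjusted p = 0.669), and 3 rose under median scaling. TP53INP1, a stress protein, rose 2.82-fold and TP53I3, an oxidoreductase, 2.21-fold, while GADD45A, a growth arrest gene, fell 2.36-fold and AEN, an apoptosis-enhancing nuclease, 1.57-fold. ZMAT3, SESN1, XPC, BAX and MDM2 lay between -0.25 and 0.13 and did not pass. The number of p53 targets that fell was 4 with the array background level as a covariate or without control replicate 1 or 3 or knockdown replicate 1, and 3 without knockdown replicate 3 or the detection filter. All counts in these lists were the same adjusted over the list alone.

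Actin cytoskeleton and SRF target genes had 5 members higher and 6 lower of 21 (median log2 change -0.10, from -0.21 to -0.01 over the settings run, adjusted p = 0.453), with the same counts adjusted over the list alone. DIAPH3, a formin, fell 3.80-fold, CALD1, an actin-binding protein of smooth muscle, 2.43-fold and TAGLN, a smooth muscle marker detected on 2 of 3 knockdown arrays, 1.95-fold. Other DIAPH3 probes gave log2 changes of -1.70, -1.20 and -1.23 against -1.93. No member rose under median scaling or with the array background level as a covariate, and 2 rose without the detection filter. MYL9, PDLIM7 and ZYX, with log2 changes of 0.54, 0.43 and 0.42, had adjusted p-values of 0.125, 0.189 and 0.436 under median scaling, where the changes were 0.36, 0.32 and 0.20, or 0.47, 0.42 and 0.31 relative to the median of all genes, and the SE was 0.192 against 0.149, 0.108 and 0.109. Their other probes gave 1.38, 1.04 and 0.18.

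Growth factor genes differed individually. In the EGF family and receptor list, 4 of 11 members rose and 3 fell, also adjusted over the list alone (median log2 change 0.02, from -0.16 to 0.20 over the settings run, adjusted p = 0.554). The lower count was 1 with the mean of a gene's probes, with the array background level as a covariate and without control replicate 1 or knockdown replicate 3. EREG and TGFA, ligands of the EGF receptor, rose 3.04-fold and at least 1.73-fold, and MET, the receptor of hepatocyte growth factor, rose 1.86-fold. ERBB3 fell at least 1.53-fold. EGFR and NRG1, at -0.34 and -0.32 (adjusted p = 0.0151 and 0.024), had other probes that moved the other way, at 0.27 for EGFR and at 0.44 and 0.75 for NRG1. The EGFR call was lost without control replicate 1 (-0.30, adjusted p = 0.0582) or knockdown replicate 3 (-0.30, 0.0659). The NRG1 call was lost without any control replicate (-0.30, -0.33 and -0.32, with 0.067, 0.0514 and 0.0518) or without knockdown replicate 2 (-0.29, 0.0566) or 3 (-0.27, 0.0986). FGF2, ERBB2, HBEGF and PDGFC lay between -0.14 and 0.20 and did not pass.

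Wnt and Notch genes had 8 members higher and 3 lower of 15 (median log2 change 0.32, from 0.11 to 0.36 over the settings run, adjusted p = 0.554), with the same counts adjusted over the list alone. HES1, a Notch target detected on 1 of 3 control arrays, rose 1.92-fold, while WNT5B, a Wnt ligand, fell 3.39-fold and DKK1, a secreted Wnt inhibitor, 2.40-fold, and HEYL, NOTCH1, JAG2 and SFRP1 lay between -0.25 and 0.21 and did not pass. Among AP-1 and immediate early genes, 7 rose and 6 fell of 15, also adjusted over the list alone (median 0.08, from -0.04 to 0.17, adjusted p = 0.669). JUNB, an AP-1 subunit also detected on 1 of 3 control arrays, rose 2.91-fold and DUSP6, a phosphatase of ERK, 2.88-fold, while MYC fell 2.30-fold, DUSP1, a phosphatase of MAP kinases, 2.27-fold and FOSL1, another AP-1 subunit, 2.12-fold. IER2 and EGR1, at -0.03 and 0.08, did not pass. Median scaling left 4 members higher in each of these lists, and with detection on all 6 arrays 5 of 10 Wnt and Notch genes rose.

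Metabolic lists were mixed. Cholesterol synthesis genes had 5 members higher and 9 lower of 20, also adjusted over the list alone (median log2 change -0.22, from -0.31 to -0.14 over the settings run, adjusted p = 0.328). INSIG1, which retains the sterol sensor in the endoplasmic reticulum, rose 2.01-fold, with a log2 change of 0.55 for its other probe, while ACAT2, an acetyl-CoA acetyltransferase, fell 2.54-fold, with -0.47 for its other probe, and IDI1, an isomerase of the pathway, fell 1.71-fold. The higher count was 3 without control replicate 3, knockdown replicate 2 or the detection filter and with the array background level as a covariate, and 2 under median scaling. Glycolysis genes had 6 members higher and 3 lower of 20, also adjusted over the list alone (median 0.12, from 0.07 to 0.17, adjusted p = 0.539), and 5 fell with array weights. SLC2A3, a glucose transporter, rose 2.69-fold and ALDOA, an aldolase, 1.70-fold (log2 change 0.77, with 0.40 for its other probe), while PFKP, a phosphofructokinase, fell 1.68-fold and SLC2A1, another glucose transporter, 1.53-fold. HK2, a hexokinase, fell 1.60-fold (log2 change -0.68, adjusted p = 0.0106, but -0.57 and 0.0556 without control replicate 2). Amino acid stress and ATF4 target genes had 4 members higher and 10 lower of 20 (5 and 11 adjusted over the list alone), with a median of -0.32 (-0.14 without the detection filter) and an adjusted p of 0.296. DDIT4, an inhibitor of mTOR signalling, rose 4.53-fold, while SLC7A5, a leucine transporter, fell 3.12-fold and MTHFD2, a mitochondrial folate enzyme, fell 2.35-fold.

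Epithelial markers had 3 members higher and 3 lower of 10, also adjusted over the list alone (camera adjusted p = 0.669), and their median log2 change of -0.04 (from -0.11 to 0.02 over the settings run) and mean of 0.14 differed in sign. CLDN7, a tight junction protein, rose 2.23-fold and KRT19, a keratin, 2.08-fold, while CLDN1, another tight junction protein, fell 1.45-fold (log2 change -0.53, adjusted p = 0.00542, and -0.39 and 0.0732 with the array background level as a covariate). TJP1, KRT7, KRT18 and EPCAM lay between -0.12 and 0.17 and did not pass, and the lower count was 1 without knockdown replicate 2 or with that covariate. Hepatocyte, endothelial and leukocyte markers were mostly below detection, and their counts were the same adjusted over the list alone. Of 24 hepatocyte markers, 4 were measured. SERPINA1, which encodes alpha-1-antitrypsin, rose 2.84-fold and ALB, which encodes albumin and was detected on 2 of 3 knockdown arrays, fell 1.39-fold, whereas the rise of CYP2E1 (log2 change 0.28, adjusted p = 0.0481, detected on 1 of 3 control arrays) was lost on leaving out any array but knockdown replicate 3 (log2 changes of 0.22 to 0.30, adjusted p of 0.0693 to 0.13). ASGR1 was at -0.14 and did not pass. Of 18 endothelial markers, 3 were measured, of which EGFL7 rose at least 1.30-fold (0.29 on the log2 scale for its other probe), and ROBO4 and ENG, at -0.21 and 0.25, did not pass. The number of endothelial markers that rose was 2 without control replicate 1. Of 17 leukocyte markers, 2 were measured, of which CD14 rose 3.23-fold and CD68, at -0.05, did not pass.

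Of 13 measured reference genes, 2 rose and 3 fell, also adjusted over the list alone (median log2 change -0.02, from -0.07 to 0.03 over the settings run, adjusted p = 0.829). B2M, the light chain of MHC class I, rose 1.43-fold and RPL13A 1.32-fold, the latter with an adjusted p of 0.194 under median scaling (log2 change 0.31, or 0.42 relative to the median of all genes, against 0.40). SDHA fell 1.60-fold, TFRC 1.40-fold and HPRT1 1.33-fold, with log2 changes of -0.68 and -0.41 for SDHA and HPRT1 and -0.28 and -0.26 for their other probes, while ACTB and GAPDH, at -0.02 and 0.02, did not pass.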

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

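The array background level as a covariate was added after seeing the data, and the other settings were planned. YAP1 fell under every setting run, with log2 changes of -2.59 to -2.30, and WWTR1 under every setting that kept its probe, with fitted changes of -1.98 to -1.31 that rest on knockdown values below detection, where the fold is known only as a bound (requiring detection on all 6 arrays removed it). Between 3913 genes (median scaling) and 5591 (array weights) passed the threshold, against 5328, and all 5328 kept their sign wherever measured, except that 5312 did with the mean of a gene's probes. Leaving out an array gave 4654 to 5121. With a replicate block the count was 5043. Same-numbered arrays did not deviate from their group means together (correlations of -0.18, -0.13 and -0.015, and 0 of the 6 arrays correlated best with its own number), so the numbers were not taken to pair the samples.

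The largest departure came with median scaling, where 1438 genes were higher against 2658 and the SE of the YAP1 level was 0.192 against 0.0936. MYL9, PDLIM7 and ZYX had that same SE. Adjusted p-values of named genes followed the size of the change (0.022 for B2M at 0.52, 0.0219 for NRG1 at -0.52). Calls lost under median scaling may reflect this shared SE as well as the scaling, and these were not separated. Relative to the median of all genes under median scaling, -0.107, list medians were -2.19 for mitosis, -0.81 for YAP and TAZ targets, 0.92 for collagens and 0.75 for interferon genes, against -2.12, -0.70, 0.88 and 0.78. Camera's direction for the reference genes reversed (median -0.0312, adjusted p = 0.911), as it did without knockdown replicate 1. The reference gene median ranged from -0.0604 to 0.0330 over the arrays left out. The medians of the p53, EGF and AP-1 lists went below 0, to -0.07, -0.16 and -0.04. Members higher under median scaling numbered 1 for YAP and TAZ targets, 3 for Hippo, 3 for p53, 0 for actin, 4 for Wnt and Notch, 4 for AP-1, 2 for cholesterol, 9 for lysosome, 5 for mesenchymal, 1 for hepatocyte and 1 for reference genes, against 3, 6, 8, 5, 8, 7, 5, 15, 8, 2 and 2. Requiring detection on all 6 arrays left fewer members to test and put the AP-1 median at -0.0267 (adjusted p = 0.937), with 19 of 21 replication genes lower, against 30 of 32, and 5 of 10 Wnt and Notch genes higher, against 8 of 15. With the mean of a gene's probes, NRG1 reversed to 0.29 (adjusted p = 0.0216), because its other probes had changes above 0, and 1 EGF list member was lower against 3. Apart from these, the cause of each change was not tested.

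With an estimated correlation, 7 lists no longer passed camera at unchanged medians: YAP and TAZ targets (-0.697), collagens (0.878), integrins (0.341), TGF-beta (0.849), NF-kB (1.03), lysosome (0.454) and mesenchymal markers (0.577). The estimate was below the preset 0.01 for YAP and TAZ targets (0.003) and mesenchymal markers (-0.0341). Their unadjusted camera p-values still rose (0.000352 to 0.0194, 0.00197 to 0.0319), so they do not measure correlation alone. For the other lists the estimate ran from 0.0803 (lysosome) to 0.15 (collagens). Under fry, which does not compare a list with other genes, 8 lists passed that had not (medians in brackets): Hippo (-0.153), p53 (0.0629), actin (-0.102), EGF (0.0236), cholesterol (-0.216), glycolysis (0.121), ATF4 (-0.319) and epithelial markers (-0.0419). Fry placed the epithelial markers higher (adjusted p = 0.0362), on the side of their mean of 0.14 and not of their median. In all other cases run, camera's direction and the side of the threshold were as reported. The covariate left 0 actin members and 3 cholesterol members higher, and 4 p53, 1 EGF, 1 epithelial and 0 lysosome members lower. Without the detection filter, which also tests dim probes, 2 actin and 3 cholesterol members were higher and 3 p53 and 0 lysosome members lower. That setting put the medians of TGF-beta, mesenchymal, ATF4, leukocyte, endothelial and hepatocyte genes at 0.42, 0.35, -0.14, 0.11, -0.04 and -0.03, against 0.85, 0.58, -0.32, 0.82, 0.25 and 0.07. With the mean of a gene's probes the integrin median was 0.56 against 0.34. Among lists that passed camera, no other setting moved a median of a tested list by over 1.5 times. In lists that did not pass, medians nearer 0 moved by more when an array was left out: p53 0.01 to 0.08, actin -0.18 to -0.04, Hippo -0.23 to -0.08, cholesterol -0.31 to -0.14, glycolysis 0.07 to 0.14, EGF -0.03 to 0.10, AP-1 0.07 to 0.16 and epithelial -0.06 to 0.02. Array weights put 5 glycolysis members lower against 3, and 1 lysosome member against 2. Single calls in lists with 1 lower member (EIF2AK2, GREM1, LOX) and the rise of CYP2E1 were lost under some settings. Among the named genes other than the siRNA targets, 86 of the comparisons with another setting lost the call with the same sign, 1 (NRG1) reversed and 2256 kept it. Slide as a block was not run, as slides were not given in the sources used here. Signal over background limits the dim genes, since 28.8% to 35.6% of probes per array were detected.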

Other observations

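The gene lists and the tests of histone genes in this part were chosen after the data were seen, as was the array background covariate, while the test of sample splits, the random lists, the split of the interferon list and the comparison of scalings were set out before their results were seen. The core genes used in the interferon split came from a list chosen after the data were seen. The p-values of the 5 lists chosen after were adjusted over those 5 alone. As these lists were chosen after the same data were seen, their p-values describe the shift and are not independent evidence for it.

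Antigen presentation genes rose along with the interferon list. Of 25 measured genes, 22 rose and 1, ERAP2, fell (log2 change -0.25, with 1.34 for its other probe), with a median of 0.90, or 0.73 with the 2 genes below detection in the controls at their bound (camera adjusted p = 1.25e-09, adjusted p = 0.0221 with an estimated correlation). Genes of MHC class II were among them. CD74, the invariant chain, rose 5.93-fold, HLA-DPA1 4.04-fold, HLA-DMB 3.95-fold and HLA-DRA 3.43-fold, with HLA-DRA going from 10.39 to 12.17 on the log2 scale. Of class I, HLA-B and TAPBP, which loads peptides, rose 3.44-fold each, with 0.49 and 1.42 for the other TAPBP probes against 1.78. The ERAP2 call (adjusted p = 0.0483) was lost on leaving out any of the 6 arrays (log2 changes of -0.28 to -0.22, adjusted p of 0.0556 to 0.13), and with the mean of its probes the gene rose (0.55, adjusted p = 0.000445). TAP2 and ERAP1, at -0.30 and 0.32, did not pass (limma adjusted p = 0.0539 and 0.0664), and the other TAP2 probe was at -0.014. Adjusted over the list alone, 23 genes rose and 2 fell. The lower count was 2 with the authors' processed values and 0 with the mean of a gene's probes. Under median scaling 20 genes rose and the median was 0.74. HLA genes are similar in sequence, and how far their probes read other family members was not tested.

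DNA repair and Fanconi anemia genes fell with the replication genes. Of 22 measured, 17 fell and none rose, with a median log2 change of -1.34, or -1.25 with 5 genes at their bound (camera adjusted p = 1.25e-09, adjusted p = 0.0221 with an estimated correlation). BARD1 fell 5.04-fold and its partner BRCA1 2.57-fold, and RAD54L fell at least 3.56-fold. With detection required on all 6 arrays, 10 of 14 fell. PARP1, PALB2, FANCL, MUS81 and XRCC2 lay between -0.20 and -0.01 and did not pass. Of 8 prostaglandin synthesis genes, 3 rose and 2 fell. Camera did not separate them from other genes (adjusted p = 0.269, adjusted p = 0.339 with an estimated correlation), while fry, which makes no such comparison, placed them higher (adjusted p = 0.000347). The list's mean was 0.85, and its median of 0.09 went to -0.11 under median scaling. Within it, beside PTGES, AKR1C3 rose at least 2.32-fold and PTGS2, the inducible cyclooxygenase, at least 1.83-fold, both from below detection, with a log2 change of 0.45 for the other PTGS2 probe, while CBR1 and PTGES3 fell (log2 changes of -0.55 and -0.49).

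Although replication genes fell, 15 of 21 measured replication-dependent histone genes rose and 2 fell (median log2 change 0.83, camera adjusted p = 5.42e-06, adjusted p = 0.0414 with an estimated correlation), while without the detection filter 16 of 69 rose and 2 fell, with a median of 0.03. H4C8, H2AC6 and H4C5 rose by 3.29, 2.10 and 2.08 on the log2 scale, with H4C5 detected on 2 of 3 control arrays, and H4C3, the brightest in the controls at 14.01, and H2BC11 fell by 2.84 and 0.37 (H2BC11 did not pass without control replicate 3, at -0.28 and an adjusted p of 0.065, or without knockdown replicate 1, at -0.32 and 0.0593). If every histone probe read all copies of its type, the H4 genes would share a change, but the highest and lowest of the 4 H4 genes that passed, of 5 measured, differed by 6.12, against a median SE of 0.113, which argues against full cross-hybridisation and leaves partial sharing open. Of the 17 that passed, 88.2% were higher, but 4 of these were detected on fewer than 3 control arrays, so their rise helped them past the detection filter. With detection required on all 6 arrays, 11 of 15 rose and 2 fell, so the rises did not rest on those 4 genes. How far the signal of these probes follows total histone mRNA, and how a loss of S phase would change it, was not measured. Because that is unknown, the share of rises does not decide whether loss of S phase was the cause, and no other biological explanation was tested.

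The interferon list's median of 0.78 lay above all 10000 random lists of matched signal (percentile 100, upper 95% bound 0.25). That argues against a small shift shared by probes of that signal. The list had already passed camera, which also compares it with other genes, so this is not separate evidence for its rise. With the array background level as a covariate the median was 0.71 (adjusted p = 1.21e-06), which argues against background as the whole cause. Innate sensing of the siRNA through type I interferon would put the core type I genes at or above the remaining members. The medians differed by -0.0015, against an SE of 0.205 for the difference of means across genes. The remaining members are interferon response genes too, so an effect of the depletion could give the same result. Sensing and an effect of the depletion cannot be told apart, since each siRNA was used in a single group. Of the 12 core genes measured, 10 rose (camera adjusted p = 7.26e-05, adjusted p = 0.0221 with an estimated correlation). All 12 belong to the interferon list, so this repeats part of its result and is not separate evidence. IFNB1, IFNA1, IFNL1, IFNL2, IFNL3 and IFNG were detected on 0 of the 6 arrays.

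The number of genes past the threshold was large. The 6 arrays make 10 splits into 3 and 3, and 10 splits are too few for a share under 0.05. Of these, 1, the real split, gave 5328 genes and the highest other gave 0. Every other split mixed the siRNA groups on each side, so a large group difference of any cause would add to the spread within its sides. The count of 0 there could be foreseen and lends no support to an effect of the siRNA. With the background level as a covariate 4349 genes passed, 4205 of them among the 5328, and the genes called kept 101.1% of their median absolute log2 change, with 100% on the same side of 0, which argues against background as the whole cause. Quantile normalisation, which gives all arrays the same distribution, may have balanced rises and falls. Median scaling moved the median change of all genes by -0.109 and the share of rises by -13.1 points, and 40.3% of genes passed under it. Its median was taken over all 47231 probes, of which 28.8% to 35.6% were detected per array, so it aligned the arrays near background. It therefore cannot show whether quantile normalisation balanced the calls. Neither scaling can show a change in total mRNA per cell, so that part stays open.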
